A study of Mus musculus with 10 samples.

How the data were processed

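RNA of 5 cell populations sorted from mammary glands of adult virgin female C57BL/6 mice was measured by RNA-seq, with 2 biological replicates of each and 10 libraries in all. Per the labels' protocols, RNA of freshly sorted cells was extracted with an RNeasy Plus kit, libraries were made with a TruSeq RNA kit, and paired-end reads of 80 bases were sequenced on a NextSeq 500. Per the submitters' processing notes, reads were assigned to genes with featureCounts on the mm10 genome, with no versions stated, and the aligner, annotation and strandedness are not given in the sources used here. The deposited values were raw counts per gene as made by the authors with featureCounts, 1 column per library. The counts of each library's own table were equal to those in the table of the whole series.

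The table held 27179 genes by Entrez gene ID. RefSeq names were found for 25275 of them and GENCODE names for 18, while 1886 had none. Those without a name took 0.387% to 2.32% of counts and were kept in the library totals and in tests. Totals ranged from 5636092 to 23093742. On the CPM scale used (counts scaled to the TMM-adjusted total of the tested genes), 3 counts correspond to 0.119 to 0.683 CPM. Gene coordinates are those of the GRCm38 annotation.

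Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr with the population as group (minimum count 10, minimum total 15), which left 15681. Normalization was by TMM, with factors from 0.779 to 1.36. A quasi-likelihood model was fitted over all 5 populations with 5 residual degrees of freedom, because 2 libraries per population give few degrees of freedom in a fit of 2 groups. The common biological coefficient of variation was 0.333. Contrasts compared ductal with stromal macrophages, each of these with the mean of the 3 dendritic cell populations, CD103+ with CD103- cells, and CD11b+ cells with the mean of both CD11b- populations, with equal weight for each population. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. These p-values measure the spread between biological replicates. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the F statistic.

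To find genes in which ductal macrophages lay above or below every other population, the largest of 4 pairwise p-values was used where all 4 fold changes had 1 sign, and 1 otherwise, before adjustment. The 10 pairs of populations were also compared as counts of calls. Distances between populations were root mean square differences in log2 CPM (prior count 2) between libraries over the tested genes, averaged over pairs of libraries. They were also taken over the 500 genes of largest difference of each pair of libraries. Principal components were computed on the 500 genes of largest variance. Where the lower side of a comparison had no count of a gene, the fold was taken against a floor of 3 counts over its libraries, which covers counting error alone. Genes with fewer than 4 counts in a compared population are given as CPM or as such a bound.

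Gene lists were written from general knowledge of the cell types before the data were examined, as were the contrasts, tests, filters and most other settings tried. The 20 lists were macrophage core, dendritic cell core, cDC1, cDC2, mature CCR7+ dendritic cells, perivascular LYVE1+ macrophages, microglia-type, lipid-associated TREM2 macrophages, lysosome, efferocytosis and complement, MHC class II, MHC class I, cell cycle, matrix remodelling, growth factors, chemokines, inflammatory NF-kB, interferon response, lipid handling and dissociation stress. Lists overlapped, so that 9 macrophage core and 9 lysosome genes were also on another list. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 20 lists within a comparison, and again with an estimated correlation and with fry. No list passed in any comparison with the estimated correlation. Members called were counted over all genes tested and adjusted over the list alone. A further 13 lists held markers of luminal and basal epithelium, adipocytes, fibroblasts, endothelium, T cells, B cells, natural killer cells, neutrophils, mast cells, plasmacytoid dendritic cells, monocytes and erythroid cells, given as summed CPM.

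Genes named in the text follow a rule set before the data were examined. For each of 5 comparisons these were up to 10 genes per direction with the largest absolute log2 fold change, among called genes whose library CPMs did not overlap between the sides and whose mean was at least 30 CPM on the higher side. For ductal macrophages against each other population up to 15 higher and 10 lower genes were taken by their smallest difference. Added to these were up to 4 members of a list with the largest absolute log2 fold change, and the genes of the sorting markers. Predicted genes without a proper symbol were left out, and some list members are not reported here.

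The pipeline was tested on simulated data with the depths and dispersions of these libraries, in which known genes of 1 population were changed 2-fold or 4-fold. Of the 4-fold changes, 42.9% were recovered for ductal against stromal macrophages, 55.1% for ductal macrophages against dendritic cells, 34.7% for ductal macrophages against each, 67.7% for stromal macrophages against dendritic cells, 50.5% for CD103+ against CD103- cells and 57.9% for CD11b+ against CD11b- cells. Of the 2-fold changes, 0% to 12.2% were recovered, so most changes of that size were missed in the simulation. It changed fewer genes than were called in the data, except between CD103+ and CD103- cells. For ductal against stromal macrophages it gave 49 calls, where the data gave 4801. With more genes called, the adjusted threshold admits larger p-values, so these shares do not measure recovery in the data. False calls numbered 6 of 49, 4 of 67, 0 of 34, 8 of 87, 3 of 56 and 6 of 72 in the same order, a larger share than the nominal 5% in 5 of these 6 tests.

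Other settings tried were DESeq2 size factors, no filter and a stricter filter on low counts (5 CPM in 2 libraries), the DESeq2 1.42.0 Wald test, limma voom, a test against a 1.5-fold change, a fit on the compared populations only, the replicate number as a block, a prior count of 0.5 for distances, and leaving out each library in turn. Chosen after the data were seen were fits without mitochondrial genes, with counts thinned at random to 5636092 per library, and with the epithelial marker level as a covariate.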

Results

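RNA was sequenced from 5 cell populations sorted from the mammary glands of adult virgin female C57BL/6 mice, with 2 biological replicates of each. The populations were ductal macrophages, which lie along the epithelium of the milk ducts, stromal macrophages of the surrounding connective tissue, and 3 kinds of dendritic cell, the antigen-presenting cells that carry antigen to lymph nodes. The dendritic cells were divided by the integrin chains CD11b and CD103 into CD11b-CD103+ cells (hereafter CD103+), CD11b-CD103- cells (hereafter CD103-) and CD11b+ cells. The labels call the replicates biological without saying whether a library came from 1 mouse or from a pool. Total counts were 5636092 and 6388106 for the ductal macrophages, 23093742 and 17998986 for the stromal macrophages, 18594628 and 22519191 for the CD103+ dendritic cells, 11703066 and 18075324 for the CD103- dendritic cells, and 15849123 and 5745085 for the CD11b+ dendritic cells (replicates 1 and 2). After a filter on low counts, 15681 genes were tested.

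The genes of the sorting markers were read first, as a check of the labels. Itgam, which encodes CD11b (gene ID 16409, chromosome 7, 128062640 to 128118491, GRCm38, protein coding), stood at 628 ± 102.5 CPM (counts scaled to the TMM-adjusted total of the tested genes, mean ± SD, n = 2 for this and later values) in the CD11b+ dendritic cells. Its level was 8.37 ± 1.53 CPM in the CD103+ and 11.1 ± 0.427 CPM in the CD103- dendritic cells, 109 ± 10.3 CPM in the stromal and 8.51 ± 1.08 CPM in the ductal macrophages. Itgae, which encodes CD103 (gene ID 16407, chromosome 11, 73090505 to 73147449, GRCm38, protein coding), stood at 165 ± 9.36 CPM in the CD103+ cells, 6.59 ± 3.95 CPM in the CD103- cells and 0.730 ± 0.524 CPM in the CD11b+ cells. In a principal component analysis of the 500 most variable genes, the components took 49.1%, 29.2% and 15.4% of the variance, and the 2 libraries of the ductal macrophages, of the stromal macrophages and of the CD11b+ cells lay next to each other. The libraries of the CD103+ and CD103- dendritic cells lay close together and were interleaved on the first component, while the ductal and stromal macrophages were apart on the second component.

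**Figure D1:**
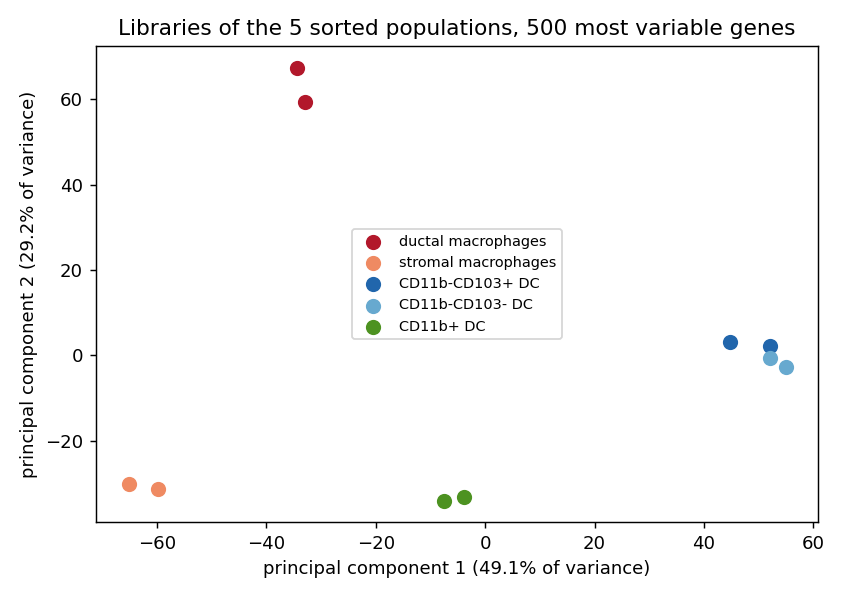
Principal component 1 (49.1% of the variance) against component 2 (29.2%) for the 10 libraries, computed on log2 CPM of the 500 most variable genes, with each point a library coloured by population. The libraries of the CD103+ and CD103- dendritic cells lie close together, and the ductal macrophages stand apart from the stromal macrophages on component 2.

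Genes higher in ductal macrophages than in all other populations included a protease, an adhesion molecule and single genes known from microglia, the macrophages of the brain. Mmp13, a collagen-cleaving metalloproteinase, stood at 505 ± 96.2 CPM in ductal macrophages, 7.09 log2 units above the nearest other population, the stromal macrophages at 3.71 ± 0.556 CPM. Vcam1, an adhesion molecule bound by the integrin VLA4, reached 3345 ± 134 CPM and lay 6.67 log2 units above the nearest population. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, reached 2218 ± 598 CPM and lay 6.78 above. The fractalkine receptor Cx3cr1 (gene ID 13051, chromosome 9, 120048683 to 120068296, GRCm38, protein coding) stood at 585 ± 9.73 CPM against at most 12.5 ± 1.54 CPM elsewhere, in the CD103- dendritic cells. The microglial genes Tmem119 and Olfml3 stood at 317 ± 52.2 and 721 ± 49.6 CPM, 5.90 and 5.79 log2 units above the nearest population.

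The test for each gene took the largest of the 4 p-values of edgeR's quasi-likelihood test against the other populations, with Benjamini-Hochberg adjustment. By this test 396 genes were higher and 185 lower in ductal macrophages than in every other population. Among the higher genes with the largest smallest difference were also Adamdec1 (7.28), B3galt5 (6.82), Cd4 (6.25), Capn3 (5.98), Lilra5 (5.72), Itgb5 (5.53), B3gnt8 (5.30), Lpcat2 (5.18) and Gdf3 (4.86), each on the log2 scale against its nearest population. Cd4, best known as the coreceptor of helper T cells, stood at 204 ± 77.7 CPM, and the integrin chain gene Itgb5 at 1168 ± 259 CPM. The adjusted p of these genes ranged from 1.80e-05 (Vcam1 and Lpcat2) to 0.0188 (B3galt5). The DESeq2 Wald test did not call Adamdec1 (adjusted p = 0.779) or B3galt5 (0.186). Left-out libraries took the adjusted p by edgeR above the threshold for B3galt5 (0.122 without ductal replicate 1, 0.214 without CD11b+ replicate 1, 0.116 without ductal replicate 2, 0.0611 without CD103+ replicate 2, 0.0654 without CD103- replicate 2 and 0.123 without CD11b+ replicate 2) and Gdf3 (0.144 without ductal replicate 1, 0.166 without CD11b+ replicate 1, 0.0667 without ductal replicate 2 and 0.145 without CD11b+ replicate 2).

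Genes lower in ductal macrophages than in every other population included a transcription factor, a scaffold protein and regulators of the actin cytoskeleton. The transcription factor Klf2, known for controlling cell trafficking, lay -3.57 log2 units from the nearest population (24.8 ± 1.87 CPM against 294 ± 89.4 CPM in the CD103- dendritic cells). The giant scaffold protein gene Ahnak (-3.96), the actin regulator genes Iqgap2 (-4.91) and Arhgap26 (-4.06), the growth factor receptor gene Fgfr1 (-4.53), Crip1 (-4.25), the adaptor gene Grap (-4.48) and Rasgrp4 (-3.63) were lower as well. Pstpip1 was counted 2 times over both ductal libraries (0.189 ± 0.267 CPM) and stood at 34.6 ± 12.2 CPM in the stromal macrophages, the nearest population. ATP6, a subunit gene of the mitochondrial genome, lay -3.72 from the nearest population, the CD11b+ dendritic cells, and mitochondrial transcripts made up 0.631% and 0.891% of the ductal counts against 1.88% to 24.8% elsewhere. Left-out libraries took the adjusted p by edgeR above the threshold for ATP6 (0.416 without ductal replicate 1, 0.105 without CD103+ replicate 1, 0.356 without CD11b+ replicate 1, 0.128 without ductal replicate 2, 0.0722 without CD103+ replicate 2 and 0.205 without CD103- replicate 2).

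The same count was made for each population. Stromal macrophages were higher than all others at 312 genes and lower at 427, and CD11b+ dendritic cells were higher at 88 and lower at 36. CD103+ dendritic cells had 0 genes in either direction and CD103- dendritic cells 0 higher and 4 lower by the same edgeR test, which required each of them to differ from the other. Between those 2 populations edgeR called 5 genes in all, described below. Of the 15681 genes tested, 1000 had an unadjusted p under 0.05, which a share of 0.05 would have if no gene differed. With 1 library left out, the 396 genes became 123 without ductal replicate 1, 227 without CD11b+ replicate 1, 221 without ductal replicate 2 and 212 without CD11b+ replicate 2, and the 185 became 58 without ductal replicate 1 and 108 without ductal replicate 2.

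The comparison of ductal with stromal macrophages asks how the macrophages at the ducts differ from those of the surrounding tissue. Ductal macrophages were higher for antigen presentation by MHC class II, for the integrin gene Itgax, which encodes CD11c, and for lysosomal genes. Stromal macrophages were higher for the genes of perivascular LYVE1+ macrophages, for interferon response genes and for early stress genes. Itgax differed by 11.79 ± 0.51 (log2 fold change ± SE, for this and later values), from 0.198 ± 0.0462 CPM in stromal to 729 ± 168 CPM in ductal macrophages. In the other direction, Retnla, which encodes the secreted protein RELM-alpha of alternatively activated macrophages (gene ID 57262, chromosome 16, 48842609 to 48844461, GRCm38, protein coding), differed by -9.83 ± 0.69, with 10.8 ± 5.90 CPM in ductal and 9930.4 ± 3473 CPM in stromal macrophages. A total of 2555 genes were higher and 2246 lower in ductal macrophages by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05.

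Several of the largest differences were of genes without a count in either stromal library, for which the fold was taken against a floor of 3 counts over the 2 libraries of the population and is a lower bound. Ductal macrophages were at least 3789-fold higher for Tlr12, a toll-like receptor gene, at least 971-fold higher for Ccr7, the chemokine receptor that guides cells to lymph nodes, and at least 557-fold higher for Il12b, the shared subunit of interleukins 12 and 23. Adgrg5 (at least 1981-fold), Creg2 (at least 487-fold), B3galt5 (at least 435-fold) and Gpr141 (at least 367-fold) were also without counts in stromal macrophages. H2-M2, a non-classical MHC class I gene, differed by 11.22 ± 0.95, and Capn3, counted 3 times over the stromal libraries, stood at 96.6 ± 15.1 CPM in ductal macrophages. Of the genes lower in ductal macrophages, Bank1 (at least 313-fold) and Trim30c (at least 164-fold) had no ductal counts. The C-type lectin genes Cd209g (-11.00 ± 0.80) and Cd209f (-10.84 ± 0.42), the scavenger receptor gene Cd163 (-10.15 ± 0.44) and the clotting factor gene F13a1 (-10.90 ± 0.82) were lower, and Ccl24, Cd209b and C6 had 1 or 2 ductal counts against 366 ± 96.4, 345 ± 78.9 and 129 ± 31.6 CPM in stromal macrophages. Reads of the near-identical Cd209, histocompatibility and immunoglobulin genes, of mitochondrial genes with nuclear copies and of overlapping or antisense genes are uncertain, since the counting may have split them and its strandedness is not given in the sources used here.

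The genes of perivascular LYVE1+ macrophages were the group with the largest shift. Of the 20 genes listed, 1 was higher, 19 lower and 0 did not pass (camera adjusted p = 5.36e-14, adjusted p = 0.166 with an estimated correlation). Over the perivascular list alone, 1 was higher and 19 lower. Besides F13a1, Cd209f, Cd163 and Retnla, described already, Ccl24 belonged to the list. The MHC class II list, of genes that present antigen to helper T cells, had all its members higher in ductal macrophages. It gave 13 higher, 0 lower and 0 not passing (camera adjusted p = 7.83e-11, adjusted p = 0.38 with an estimated correlation). Over the MHC class II list alone, 13 were higher and 0 lower. H2-Oa (7.45 ± 0.68), H2-Ab1 (4.82 ± 0.53), the invariant chain gene Cd74 (4.59 ± 0.54) and H2-Eb1 (4.39 ± 0.45) led this list, and Cd74 alone stood at 115707 ± 3020.4 CPM in ductal macrophages. Of 15 MHC class I pathway genes, 11 were higher, 0 lower and 4 did not pass (camera adjusted p = 4.07e-05, adjusted p = 0.38 with an estimated correlation). Over the MHC class I list alone, 11 were higher and 0 lower, led by Tapbp (2.41 ± 0.33), Erap1 (1.93 ± 0.25) and B2m (1.74 ± 0.39). Of 23 lysosomal genes, 13 were higher, 1 lower and 9 did not pass (camera adjusted p = 1.25e-06, adjusted p = 0.38 with an estimated correlation). Over the lysosome list alone, 15 were higher and 1 lower, with Ctss (3.93 ± 0.43) and Psap (3.42 ± 0.37) among the higher genes.

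Interferon response genes were lower in ductal macrophages. Of the 18 listed, 0 were higher, 16 lower and 2 did not pass (camera adjusted p = 1.08e-07, adjusted p = 0.166 with an estimated correlation). Over the interferon response list alone, 1 was higher and 16 lower, and Ifit3 (-4.42 ± 0.28), Ifit1 (-3.66 ± 0.42), Oasl2 (-3.63 ± 0.29) and Usp18 (-3.18 ± 0.30) had the largest differences. Early response and heat shock genes that rise during tissue dissociation were lower too. Of 17 such genes, 0 were higher, 14 lower and 3 did not pass (camera adjusted p = 5.82e-07, adjusted p = 0.38 with an estimated correlation). Over the dissociation stress list alone, 0 were higher and 14 lower, led by Ier3 (-4.10 ± 0.39), Egr1 (-3.42 ± 0.40), Hspa1a (-2.74 ± 0.54) and Jun (-2.52 ± 0.40). The stromal libraries also held mitochondrial transcripts at 24.8% and 23.1% of counts, against 0.631% and 0.891% in the ductal libraries. Summed over 6 adipocyte markers, the stromal libraries stood at 427 and 457 CPM and the ductal libraries at 5.01 and 14.6 CPM.

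Microglia-type genes were divided between the populations. Of 13 tested, 6 were higher, 1 lower and 6 did not pass (camera adjusted p = 0.0349, adjusted p = 0.38 with an estimated correlation). Over the microglia-type list alone, 6 were higher and 3 lower. Cx3cr1 (7.02 ± 0.81), Tmem119 (5.90 ± 0.37) and Olfml3 (5.79 ± 0.72) were higher in ductal macrophages and Fcrls (-5.84 ± 0.79) was lower. The list of lipid-associated TREM2 macrophage genes gave 11 higher, 2 lower and 5 not passing (camera adjusted p = 0.00118, adjusted p = 0.38 with an estimated correlation). Over the TREM2 list alone, 11 were higher and 2 lower. Besides Itgax, the cystatin gene Cst7 (5.46 ± 1.07) and the receptor tyrosine kinase gene Axl (4.83 ± 0.40) were higher, while the growth factor gene Igf1 (-5.94 ± 0.46) was lower. Among 21 matrix remodelling genes, 10 were higher, 1 lower and 10 did not pass (camera adjusted p = 0.0424, adjusted p = 0.38 with an estimated correlation). Over the matrix remodelling list alone, 10 were higher and 5 lower. Mmp12, the macrophage elastase, differed by 7.93 ± 0.59 and Mmp13 by 7.09 ± 0.67, while Mmp9, with 3 ductal counts, stood at 73.3 ± 3.24 CPM in stromal macrophages. For lists of microglia-type and matrix genes the camera call at the preset correlation depended on single libraries, at adjusted p = 0.0576 without ductal replicate 2 and 0.0726 without stromal replicate 2 for the microglia-type list, and at 0.107 without stromal replicate 1 and 0.0653 without ductal replicate 2 for the matrix list.

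Chemokine genes went both ways. Of 20, 5 were higher, 10 lower and 5 did not pass (camera adjusted p = 0.114 at the preset correlation). Over the chemokines list alone, 7 were higher and 10 lower. The monocyte-attracting Ccl8 (2.14 ± 2.06 CPM in ductal and 1144 ± 170.4 CPM in stromal macrophages) and Ccl7 (-6.60 ± 0.48) were lower in ductal macrophages, and Ccl22 (5.67 ± 0.92) was higher. Among 15 inflammatory genes of the NF-kB pathway, 8 were higher, 3 lower and 4 did not pass (camera adjusted p = 0.0219, adjusted p = 0.38 with an estimated correlation). Over the inflammatory list alone, 8 were higher and 3 lower. The interleukin genes Il1b (6.92 ± 0.48) and Il1a (5.63 ± 0.91) were higher and Il15 (-4.38 ± 0.49) was lower. Of 24 cell cycle genes, 6 were higher, 0 lower and 18 did not pass (camera adjusted p = 0.00201, adjusted p = 0.394 with an estimated correlation). Lipid handling genes gave 8 higher, 1 lower and 4 not passing (camera adjusted p = 0.00936 and 0.38 in the same order). Efferocytosis and complement genes gave 10 higher, 3 lower and 7 not passing (camera adjusted p = 0.0235 and 0.38). The efferocytosis call was lost without stromal replicate 2. Of 24 macrophage core genes, 7 were higher, 2 lower and 15 did not pass (camera adjusted p = 0.0227, adjusted p = 0.399 with an estimated correlation). Over the macrophage core list alone, 7 were higher and 3 lower, led by Csf1r (2.99 ± 0.48), the receptor for the macrophage growth factor CSF1, and by the endotoxin coreceptor gene Cd14 (2.79 ± 0.44). That call went to an adjusted p of 0.16 without stromal replicate 2.

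Genes usually found in dendritic cells were more often called higher than lower in ductal macrophages, except for the list of type 2 conventional dendritic cells. Of 21 dendritic cell core genes, 11 were higher, 4 lower and 6 did not pass (camera adjusted p = 0.00763, adjusted p = 0.38 with an estimated correlation). Over the dendritic cell core list alone, 11 were higher and 4 lower. P2ry10 (6.96 ± 0.67) and Runx3 (6.28 ± 0.33) were higher, as was Cadm1 (6.31 ± 0.49), an adhesion molecule gene of the list of type 1 conventional dendritic cells (cDC1). Of 16 cDC1 genes, 7 were higher, 3 lower and 6 did not pass (camera adjusted p = 0.0466, adjusted p = 0.38 with an estimated correlation). Over the cDC1 list alone, 8 were higher and 5 lower. The camera adjusted p of this list at the preset correlation was 0.0542 without ductal replicate 2 and 0.133 without stromal replicate 2. Of 21 genes of mature CCR7+ dendritic cells, 9 were higher, 3 lower and 9 did not pass (camera adjusted p = 0.0459, adjusted p = 0.534 with an estimated correlation). Over the mature CCR7+ list alone, 11 were higher and 4 lower. Its camera call was lost without ductal replicate 2 and without stromal replicate 2. Of 12 genes of type 2 conventional dendritic cells (cDC2), 1 was higher, 5 lower and 6 did not pass (camera adjusted p = 0.0612 at the preset correlation). Over the cDC2 list alone, 1 was higher and 5 lower. That list had a camera adjusted p, at the preset correlation, of 0.0445 without ductal replicate 1 and 0.0230 without stromal replicate 2. Leaving out 1 library moved the 2555 higher genes to 1555 without ductal replicate 1, and the 2246 lower genes to 981 without ductal replicate 1 and 1349 without ductal replicate 2.

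**Figure D2:**
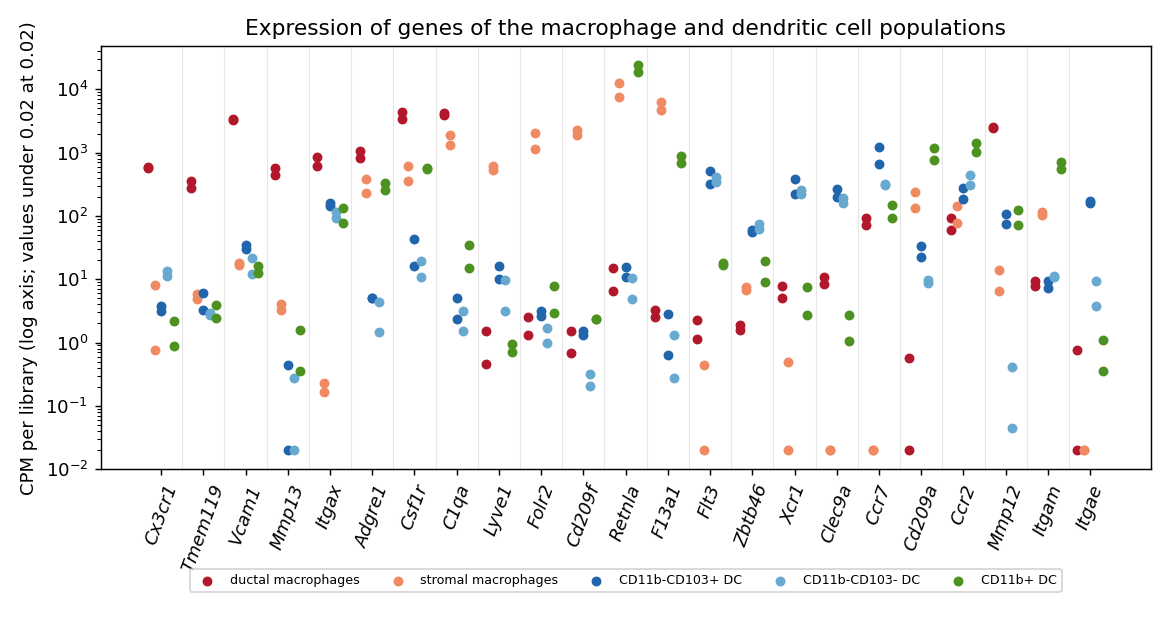
CPM of 23 genes of the macrophage and dendritic cell populations on a log axis, with each point a library coloured by population and values under 0.02 drawn at 0.02. The ductal macrophages lead for Cx3cr1, Tmem119, Vcam1 and Mmp13, the stromal macrophages for Lyve1, Folr2 and Cd209f, and the CD11b- dendritic cells for Flt3, Xcr1 and Clec9a.

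Set against the mean of the 3 dendritic cell populations, ductal macrophages were higher for macrophage and lysosomal genes and for complement, and lower for dendritic cell and cell cycle genes. Ms4a7, a gene of tissue macrophages, differed by 10.68 ± 0.37 and Mmp13 by 10.48 ± 0.50. The complement genes C1qa (9.45 ± 0.39) and C1qc (9.39 ± 0.35) were also higher, with C1qa at 4103 ± 213 CPM in ductal macrophages and at most 24.6 ± 13.5 CPM among dendritic cells. Dendritic cells were higher for Btla, an inhibitory receptor gene with 380.3 ± 115 CPM in CD103+ dendritic cells and 2 counts over the ductal libraries. By edgeR's quasi-likelihood test, 2355 genes were higher and 1822 lower in ductal macrophages.

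Other genes with large differences were near or at 0 in at least 1 dendritic cell population and are given as levels in ductal macrophages. Adamdec1 stood at 166 ± 6.85 CPM, Lilra5 at 234 ± 42.6, Gdf3 at 136 ± 28.8, Capn3 at 96.6 ± 15.1, Ms4a14 at 90.9 ± 36.0 and the potassium channel gene Kcnj10 at 32.5 ± 4.37 CPM, where the mean over the dendritic cells was at most 1.60 CPM (Gdf3). Among the genes lower in ductal macrophages, Gcsam (at least 242-fold), Upb1 (at least 147-fold) and Apol7c (at least 105-fold) had no ductal counts. Cd226, Tiam1, Kmo and Igkc had 1 ductal count each, Pstpip1 had 2 and Septin3 had 3, against means over the dendritic cells of 109, 60.7, 55.8, 66.6, 73.7 and 183 CPM. Limma voom did not call Apol7c (adjusted p = 0.0621) or Igkc (0.165), and the Apol7c level differed between the CD103+ libraries, as given below. Left-out libraries took the adjusted p by edgeR above the threshold for Gcsam (0.0604 without CD11b+ replicate 1).

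All 24 macrophage core genes passed. The list gave 24 higher, 0 lower and 0 not passing (camera adjusted p = 9.42e-19, adjusted p = 0.171 with an estimated correlation). Over the macrophage core list alone, 24 were higher and 0 lower. The RNA sensor gene Tlr7 (7.49 ± 0.53), the complement receptor gene C5ar1 (7.48 ± 0.35), the antibody receptor gene Fcgr1 (7.39 ± 0.34) and Csf1r (5.95 ± 0.35) led. Of 23 lysosomal genes, 22 were higher, 0 lower and 1 did not pass (camera adjusted p = 2.73e-15, adjusted p = 0.171 with an estimated correlation). Over the lysosome list alone, 23 were higher and 0 lower, with the protease genes Ctsb (3.80 ± 0.26), Ctsa (3.73 ± 0.21) and Ctsd (3.54 ± 0.29). The list of efferocytosis and complement genes, which serve the uptake of dying cells, gave 12 higher, 2 lower and 6 not passing (camera adjusted p = 1.93e-05, adjusted p = 0.222 with an estimated correlation). Over the efferocytosis list alone, 12 were higher and 3 lower. Besides the complement genes, the scavenger receptor gene Msr1 (7.09 ± 0.24) stood out. Of 13 microglia-type genes, 10 were higher, 0 lower and 3 did not pass (camera adjusted p = 2.30e-07, adjusted p = 0.171 with an estimated correlation). Over the microglia-type list alone, 10 were higher and 0 lower, with Olfml3 (7.79 ± 0.49), Trem2 (7.17 ± 0.44) and Cx3cr1 (7.12 ± 0.51). Genes of lipid-associated TREM2 macrophages gave 12 higher, 2 lower and 4 not passing (camera adjusted p = 1.93e-05, adjusted p = 0.192 with an estimated correlation). Over the TREM2 list alone, 12 were higher and 3 lower, and Apoe (7.83 ± 0.41) reached 38783 ± 2055 CPM in ductal macrophages.

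Dendritic cell core genes were mostly lower in ductal macrophages. Of 21, 2 were higher, 15 lower and 4 did not pass (camera adjusted p = 1.89e-05, adjusted p = 0.171 with an estimated correlation). Over the dendritic cell core list alone, 2 were higher and 15 lower. Flt3, the receptor gene that drives dendritic cell development, differed by -6.32 ± 0.56, at 1.70 ± 0.800 CPM in ductal macrophages and 417 ± 146 CPM in CD103+ cells. Nectin1 and Bcl11a had 0 and 1 ductal counts. For the cDC1 list, 1 was higher, 11 lower and 4 did not pass (camera adjusted p = 1.73e-05, adjusted p = 0.171 with an estimated correlation). Over the cDC1 list alone, 1 was higher and 12 lower, and Cd24a (-4.88 ± 0.39) was among the lower genes. For the list of mature dendritic cells that express CCR7, 1 was higher, 12 lower and 8 did not pass (camera adjusted p = 0.00109, adjusted p = 0.458 with an estimated correlation). Over the mature CCR7+ list alone, 1 was higher and 13 lower, with Cacnb3 (-5.60 ± 0.60) and Tnfrsf4 (-4.54 ± 0.75). Limma voom did not call Tnfrsf4 (adjusted p = 0.120). Cell cycle genes were lower in ductal macrophages. Of 24, 0 were higher, 18 lower and 6 did not pass (camera adjusted p = 2.63e-08, adjusted p = 0.24 with an estimated correlation). Over the cell cycle list alone, 0 were higher and 21 lower, led by Ube2c (-4.06 ± 0.41), Plk1 (-3.40 ± 0.39) and Ccna2 (-2.86 ± 0.27). Ccna2, which encodes cyclin A2, stood at 10.9 ± 2.60 CPM in ductal macrophages and between 55.6 ± 6.73 and 112 ± 30.6 CPM in the dendritic cells.

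Growth factor genes were in part higher in ductal macrophages. Of 16, 9 were higher, 1 lower and 6 did not pass (camera adjusted p = 0.0223, adjusted p = 0.24 with an estimated correlation). Over the growth factors list alone, 9 were higher and 1 lower, led by hepatocyte growth factor, Hgf (4.26 ± 0.33), by Il10 (4.20 ± 0.28) and by Pdgfa (3.72 ± 0.21). For lipid handling genes, 8 were higher, 1 lower and 4 did not pass (camera adjusted p = 5.34e-04, adjusted p = 0.24 with an estimated correlation). Over the lipid handling list alone, 8 were higher and 2 lower, with the cholesterol exporter gene Abca1 at 4.51 ± 0.30 and the nuclear receptor gene Nr1h3 at 4.42 ± 0.48. Inflammatory genes gave 8 higher, 1 lower and 6 not passing (camera adjusted p = 0.00824, adjusted p = 0.397 with an estimated correlation). Over the inflammatory list alone, 9 were higher and 3 lower, with Il1a (6.13 ± 0.59), Tnf (3.45 ± 0.31) and Ptgs2 (3.17 ± 0.30). For the MHC class II list, 8 were higher, 2 lower and 3 did not pass (camera adjusted p = 0.0223, adjusted p = 0.58 with an estimated correlation). Over the MHC class II list alone, 8 were higher and 2 lower. Its members differed in direction, as Lgmn (4.51 ± 0.18) and Ctss (3.52 ± 0.29), both proteases, were higher and H2-Ob (-2.06 ± 0.26) was lower. The dissociation stress list gave 0 higher, 9 lower and 8 not passing (camera adjusted p = 0.00109, adjusted p = 0.397 with an estimated correlation). Over the dissociation stress list alone, 0 were higher and 11 lower. Without 1 library, the 2355 higher genes became 1230 without ductal replicate 1, and the 1822 lower genes 755 without ductal replicate 1 and 1068 without ductal replicate 2.

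Stromal macrophages, set against the same mean of the dendritic cells, were higher for LYVE1+ perivascular macrophage, interferon and chemokine genes and lower for MHC class II and cell cycle genes. The lectin gene Cd209f differed by 11.05 ± 0.25, the chemokine gene Ccl8 by 9.96 ± 0.49, the ficolin gene Fcna by 9.53 ± 0.32, and Folr2, which encodes a folate receptor, by 9.19 ± 0.36. Folr2 stood at 1578 ± 605 CPM in stromal macrophages and at most 5.43 ± 3.49 CPM in dendritic cells. Ccr7 had no stromal counts and was at least 5454-fold lower than the mean of the dendritic cells. By edgeR's quasi-likelihood test 3177 genes were higher and 2851 lower.

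Further genes at the top were Cd209g (11.65 ± 0.47), F13a1 (9.04 ± 0.46) and Pf4 (8.84 ± 0.27), and C6, Mmp9 and Ms4a14 stood at 129 ± 31.6, 73.3 ± 3.24 and 37.2 ± 17.7 CPM in stromal macrophages with at least 1 dendritic cell population at 0 counts. No counts were found in stromal macrophages for Il12b (at least 1594-fold lower), Clec9a (at least 1620.5-fold), Adgrg5 (at least 394-fold), Gpr141 (at least 455-fold), Ly75 (at least 545-fold), Cd8a (at least 561-fold), Itgae (at least 678-fold) and Apol7c (at least 385-fold). Klrb1b had 1 stromal count and a mean of 62.5 CPM over the dendritic cells.

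All 20 perivascular LYVE1+ macrophage genes passed, and the list gave 20 higher, 0 lower and 0 not passing (camera adjusted p = 2.43e-17, adjusted p = 0.072 with an estimated correlation). Over the perivascular list alone, 20 were higher and 0 lower. Macrophage core genes gave 23 higher, 0 lower and 1 not passing (camera adjusted p = 7.24e-13, adjusted p = 0.111 with an estimated correlation). Over the macrophage core list alone, 23 were higher and 0 lower, with Fcgr1 (7.39 ± 0.34), C5ar1 (6.97 ± 0.35) and Tlr7 (6.16 ± 0.52) highest. Interferon response genes gave 15 higher, 1 lower and 2 not passing (camera adjusted p = 7.01e-08, adjusted p = 0.072 with an estimated correlation). Over the interferon response list alone, 15 were higher and 1 lower, led by Ifit3 (4.21 ± 0.18), Ifit2 (3.79 ± 0.31) and Oasl2 (3.65 ± 0.19). Chemokine genes gave 14 higher, 5 lower and 1 not passing (camera adjusted p = 0.0017, adjusted p = 0.323 with an estimated correlation). Over the chemokines list alone, 14 were higher and 5 lower, and besides Ccl8 the genes Ccl12 (8.70 ± 0.31) and Ccl24 (7.90 ± 0.36) were higher while Ccl22 (-7.86 ± 0.94) was lower. Dissociation stress genes gave 12 higher, 1 lower and 4 not passing (camera adjusted p = 3.85e-04, adjusted p = 0.324 with an estimated correlation). Over the dissociation stress list alone, 12 were higher and 1 lower, with Egr1 at 2.79 ± 0.27 and Ier3 at 2.05 ± 0.26. The same stromal libraries held 24.8% and 23.1% mitochondrial counts, against 1.88% to 6.29% in the dendritic cells.

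In the other direction, the MHC class II list gave 1 higher, 11 lower and 1 not passing (camera adjusted p = 1.68e-06, adjusted p = 0.323 with an estimated correlation). Over the MHC class II list alone, 1 was higher and 11 lower. H2-Oa (-5.78 ± 0.62), H2-Ob (-5.26 ± 0.32), H2-DMb2 (-5.15 ± 0.25) and H2-Ab1 (-3.73 ± 0.47) were lowest. For MHC class I pathway genes, 0 were higher, 10 lower and 5 did not pass (camera adjusted p = 5.26e-04, adjusted p = 0.35 with an estimated correlation). Over the MHC class I list alone, 0 were higher and 10 lower, with the peptide transporter genes Tap1 (-2.96 ± 0.26) and Tap2 (-2.47 ± 0.24). For cell cycle genes, 0 were higher, 23 lower and 1 did not pass (camera adjusted p = 1.69e-12, adjusted p = 0.207 with an estimated correlation). Over the cell cycle list alone, 0 were higher and 23 lower, with Plk1 (-4.23 ± 0.38), Ccna2 (-4.22 ± 0.29) and Mki67 (-3.78 ± 0.35). Dendritic cell core genes gave 0 higher, 18 lower and 3 not passing (camera adjusted p = 1.69e-12, adjusted p = 0.072 with an estimated correlation). Over the dendritic cell core list alone, 0 were higher and 18 lower, with Flt3 (-9.23 ± 0.64) and P2ry10 (-8.36 ± 0.68). The cDC1 list gave 0 higher, 15 lower and 1 not passing (camera adjusted p = 1.97e-09, adjusted p = 0.072 with an estimated correlation). Over the cDC1 list alone, 0 were higher and 15 lower, with Xcr1 at -8.14 ± 0.73.

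CD11b+ dendritic cells, compared with the mean of the CD103+ and CD103- cells, were higher for cDC2 genes and for many macrophage genes, and lower for cDC1 genes. Retnla reached 21359 ± 3767 CPM in CD11b+ cells and differed by 11.07 ± 0.52. Fcrls, also found in microglia, differed by 12.22 ± 0.75, the mannose receptor gene Mrc1 by 8.16 ± 0.32 and the chemokine gene Ccl9 by 8.12 ± 0.29. Clec9a, the cDC1 receptor gene for dead cells, differed by -6.58 ± 0.40, from 233 ± 52.4 CPM in CD103+ and 177 ± 24.4 CPM in CD103- cells to 1.91 ± 1.18 CPM in CD11b+ cells. By edgeR's quasi-likelihood test 2202 genes were higher and 1727 lower in CD11b+ cells.

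Also higher were F13a1 (9.33 ± 0.56), the clotting factor gene F10 (8.52 ± 0.81), the transporter gene Slc13a3 (8.46 ± 0.35) and the lectin gene Clec4a3 (8.35 ± 0.39). Btbd17 and Acod1, the latter encoding the enzyme that makes itaconate, stood at 33.1 ± 11.6 and 35.9 ± 23.6 CPM in CD11b+ cells with 1 CD11b- population at 0 counts. Lower were Gpr141b (-8.54 ± 0.82), Gcsam (-8.54 ± 0.84), Snx22 (-7.64 ± 0.33), Gpr33 (-7.15 ± 0.96), Cd8a (-6.76 ± 0.59), Dnase1l3 (-6.75 ± 0.58), Parvg (-6.47 ± 0.72) and Sema4f (-6.06 ± 0.46). The immunoglobulin gene Ighg2c had no counts in CD11b+ cells and was at least 281-fold lower. Left-out libraries took the adjusted p by edgeR above the threshold for Ighg2c (0.131 without CD11b+ replicate 1 and 0.0956 without CD11b+ replicate 2).

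Of 12 cDC2 genes, 8 were higher, 0 lower and 4 did not pass (camera adjusted p = 1.38e-04, adjusted p = 0.272 with an estimated correlation). Over the cDC2 list alone, 8 were higher and 1 lower, led by the lectin genes Mgl2 (6.12 ± 0.25), Cd209a (5.93 ± 0.35) and Clec4a2 (5.45 ± 0.29). Of 16 cDC1 genes, 1 was higher, 13 lower and 2 did not pass (camera adjusted p = 8.55e-09, adjusted p = 0.152 with an estimated correlation). Over the cDC1 list alone, 1 was higher and 13 lower, and Gcsam, Snx22, Cd8a and Clec9a, given above, were among them. Macrophage core genes gave 20 higher, 0 lower and 4 not passing (camera adjusted p = 6.66e-12, adjusted p = 0.204 with an estimated correlation). Over the macrophage core list alone, 20 were higher and 0 lower. The antibody receptor gene Fcgr3 (6.58 ± 0.27), Adgre1, which encodes F4/80 (6.27 ± 0.37), C5ar1 (5.06 ± 0.40) and Csf1r (4.74 ± 0.40) led. Dendritic cell core genes gave 0 higher, 16 lower and 5 not passing (camera adjusted p = 8.57e-08, adjusted p = 0.152 with an estimated correlation). Over the dendritic cell core list alone, 0 were higher and 17 lower, and Btla (-5.65 ± 0.74) and Flt3 (-4.51 ± 0.46) led the lower genes. For the perivascular LYVE1+ list, 11 were higher, 4 lower and 5 did not pass (camera adjusted p = 0.00251, adjusted p = 0.504 with an estimated correlation). Over the perivascular list alone, 11 were higher and 4 lower, and besides Retnla, F13a1 and Mrc1, Ccl24 (7.67 ± 0.45) was higher.

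Chemokine genes gave 11 higher, 4 lower and 5 not passing (camera adjusted p = 4.10e-04, adjusted p = 0.353 with an estimated correlation). Over the chemokines list alone, 11 were higher and 4 lower, and besides Ccl9 the genes Ccl24, Ccl2 (5.28 ± 0.27) and Ccl7 (5.27 ± 0.33) were higher. Matrix remodelling genes gave 12 higher, 1 lower and 8 not passing (camera adjusted p = 4.10e-04, adjusted p = 0.353 with an estimated correlation). Over the matrix remodelling list alone, 12 were higher and 3 lower, with fibronectin, Fn1, at 6.34 ± 0.49 and the urokinase receptor gene Plaur at 3.68 ± 0.20, and Mmp12 was also higher (4.50 ± 0.44). Mmp12 stood at 97.9 CPM in CD11b+, 91.7 CPM in CD103+ and 0.230 CPM in CD103- cells, so its difference came from the low level in CD103- cells. Lysosomal genes gave 14 higher, 0 lower and 9 not passing (camera adjusted p = 3.81e-06, adjusted p = 0.469 with an estimated correlation). Over the lysosome list alone, 15 were higher and 0 lower, with Ctsd (4.11 ± 0.34) and Ctsa (2.42 ± 0.23). The lipid handling list gave 6 higher, 3 lower and 4 not passing (camera adjusted p = 0.137 at the preset correlation). Over the lipid handling list alone, 7 were higher and 3 lower, of which lipoprotein lipase, Lpl (6.27 ± 0.39), and the lipid droplet gene Plin2 (3.45 ± 0.21) were highest. The camera adjusted p of this list was 0.0471 without CD103- replicate 1. The 2202 higher genes became 1141 without CD11b+ replicate 1 and 1199 without CD11b+ replicate 2 with 1 library left out, and the 1727 lower genes 660 without CD11b+ replicate 1 and 558 without CD11b+ replicate 2.

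**Figure D3:**
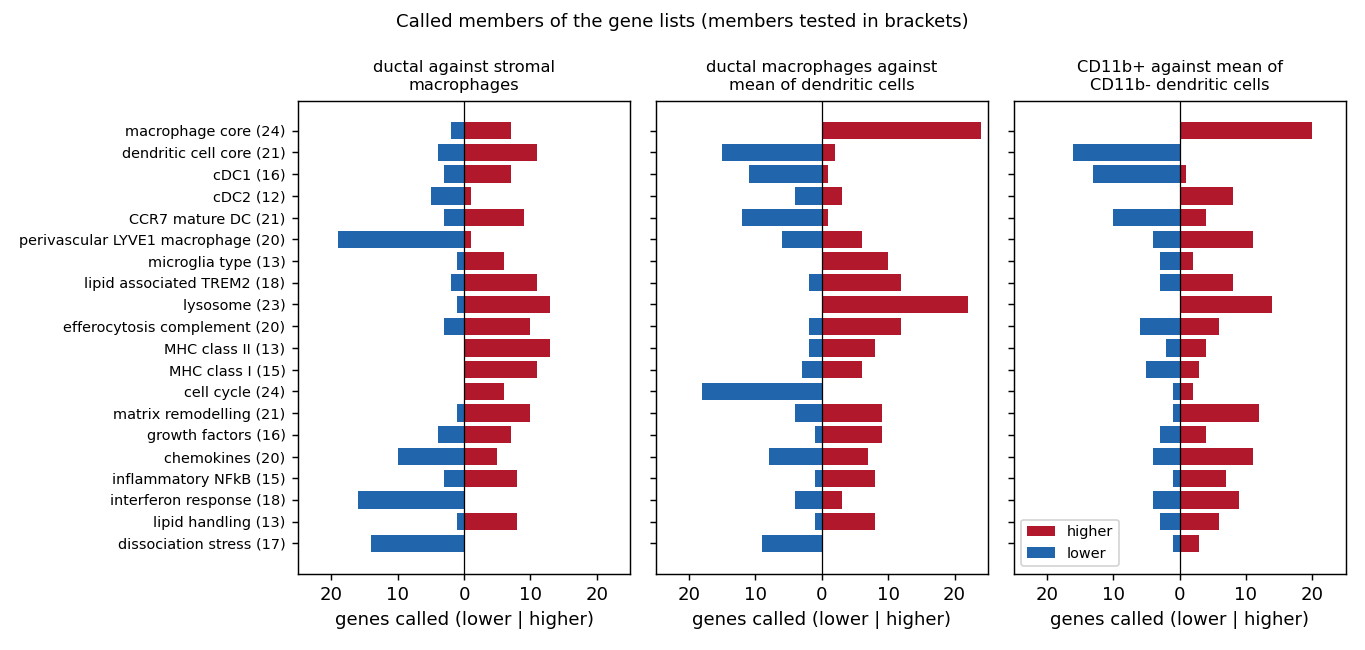
Number of genes called higher (red, to the right) and lower (blue, to the left) in each of 20 gene lists, with the number of members tested in brackets, for ductal against stromal macrophages, ductal macrophages against the mean of the dendritic cells, and CD11b+ against the mean of the CD11b- dendritic cells. All 24 macrophage core genes are higher in ductal macrophages than in dendritic cells, and 19 of 20 perivascular LYVE1+ genes are lower in ductal than stromal macrophages.

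The CD103+ and CD103- dendritic cells, both without CD11b, differed at few genes. Mmp12 (gene ID 17381, chromosome 9, 7344397 to 7360461, GRCm38, protein coding) was higher in CD103+ cells by 8.80 ± 0.70 (adjusted p = 0.00126 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at 91.7 ± 24.2 CPM against 0.230 ± 0.261 CPM. The lectin gene Mgl2 was higher by 3.75 ± 0.32, at 24.0 ± 1.84 CPM against 1.82 ± 0.652 CPM. Itgae, the sorting marker, was higher by 4.66 ± 0.53. Clec4n (4.04 ± 0.53) and Ms4a6d (2.37 ± 0.31), which fell outside the rule for naming genes and are named here because only 5 genes were called, were the others. Left-out libraries took the adjusted p by edgeR above the threshold for Itgae (0.0813 without CD103+ replicate 2 and 0.173 without CD103- replicate 2), Clec4n (0.0523 without CD103+ replicate 1, 0.128 without CD103- replicate 1 and 0.497 without CD103- replicate 2) and Ms4a6d (0.112 without CD103+ replicate 2 and 0.663 without CD103- replicate 2). Clec4n and Ms4a6d were also not called by limma voom (adjusted p = 0.227 and 0.155), against a 1.5-fold change (0.0616 and 0.0992 by edgeR) or in a fit of the compared populations only (0.115 and 0.215 by edgeR). With the replicate number as a block, Itgae (adjusted p = 0.0578 by edgeR) and Ms4a6d (0.124) were not called.

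In total 5 genes were higher and 0 lower by edgeR. Of 15681 genes, 1000 had an unadjusted p under 0.05, most of which would be expected even if no gene differed. DESeq2 called 119 higher and 31 lower, and limma voom 3 higher and 1 lower. Without 1 library, the higher genes numbered 18 without CD103+ replicate 1, 9 without CD103+ replicate 2 and 2 without CD103- replicate 2, and the lower genes 11 without CD103- replicate 1. These 11 included the B cell genes Ms4a1, Cd79a and Cd79b, whose counts were high in CD103- replicate 2.

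The cDC1 list, which both populations express, had 0 of 16 members called over all genes tested and 0 adjusted over the list alone by edgeR (camera adjusted p = 0.394 at the preset correlation, and 0.0408 without CD103+ replicate 2). Clec9a stood at 233 ± 52.4 CPM in CD103+ and 177 ± 24.4 CPM in CD103- cells, the adhesion gene Cadm1 at 416 ± 174 and 204 ± 4.21 CPM, and Irf8, a transcription factor gene of this lineage, at 882 ± 164 and 1167 ± 76.8 CPM. Of the 21 genes of mature CCR7+ dendritic cells, 0 were called over all genes tested, while 17 were higher and 0 lower adjusted over the list alone (camera adjusted p = 4.78e-19, adjusted p = 0.268 with an estimated correlation). Among these, Ccl5, a chemokine gene, stood at 372 ± 353 CPM in CD103+ and 30.3 ± 10.1 CPM in CD103- cells (list-alone adjusted p = 0.00189 by edgeR), Cacnb3 at 169 ± 103.5 and 34.3 ± 1.64 CPM (list-alone adjusted p = 0.00185), Socs2 at 56.8 ± 22.7 and 17.2 ± 1.29 CPM, and Apol7c at 88.5 ± 71.8 and 8.49 ± 1.96 CPM. The CD103+ libraries stood apart, with Ccl5 at 122 CPM in replicate 1 and 622 CPM in replicate 2, Cacnb3 at 95.4 and 242 CPM, and Apol7c at 37.8 and 139 CPM. For cell cycle genes, 0 were called over all genes tested or adjusted over the list alone, and camera called the list lower in CD103+ cells only at the preset correlation (camera adjusted p = 1.90e-09, adjusted p = 0.268 with an estimated correlation). Ccna2 stood at 55.6 ± 6.73 CPM in CD103+ and 112 ± 30.6 CPM in CD103- cells. The perivascular LYVE1+ list had 0 genes called over all genes and 3 higher adjusted over the list alone (camera adjusted p = 1.27e-06, adjusted p = 0.268 with an estimated correlation). By fry none of these 3 lists was called, with adjusted p = 0.190 for the mature dendritic cell list and 0.194 for each of the other two.

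Between pairs of populations, edgeR called 4801 genes for ductal and stromal macrophages, 3747 for ductal macrophages and CD103+ cells, 3597 for ductal macrophages and CD103- cells, and 3650 for ductal macrophages and CD11b+ cells. For stromal macrophages the counts were 5263 against CD103+ cells, 5542 against CD103- cells and 4097 against CD11b+ cells. CD11b+ cells differed from CD103+ cells at 3257 genes and from CD103- cells at 2752. As a distance without a test, the root mean square difference in log2 CPM from ductal macrophages over the tested genes was 1.88 to stromal macrophages, 1.73 to CD103+ cells, 1.75 to CD103- cells and 1.68 to CD11b+ cells. Single pairs of libraries overlapped when both ductal libraries were pooled, at 1.78 to 2.00 for stromal macrophages and 1.60 to 1.79 for CD11b+ cells. From ductal replicate 1, the stromal libraries lay at 1.95 and 2.00 and the dendritic cell libraries at 1.73 to 1.88. From ductal replicate 2, the stromal libraries lay at 1.78 and 1.80 and the dendritic cell libraries at 1.60 to 1.69. Both stromal libraries were thus the farthest from each ductal library over the tested genes. Over the 500 genes of largest difference, pairs ranged from 5.81 to 6.30 (stromal), 5.28 to 6.06 (CD103+), 5.61 to 6.20 (CD103-) and 5.61 to 6.02 (CD11b+). There, CD103- replicate 2 lay farther from ductal replicate 2 (5.88) than stromal replicate 2 did (5.81). Which dendritic cells lay nearest was therefore not settled. Left-out libraries moved some counts by more than 1.5 times. The count for ductal macrophages and CD103+ cells was 1714 without ductal replicate 1, 2145 without CD103+ replicate 1 and 2453 without CD103+ replicate 2. The count for ductal macrophages and CD103- cells was 1914 without ductal replicate 1. The count for ductal macrophages and CD11b+ cells was 1740 without ductal replicate 1, 2009 without CD11b+ replicate 1, 2385 without ductal replicate 2 and 1922 without CD11b+ replicate 2. The count for stromal macrophages and CD103+ cells was 3316 without CD103+ replicate 1 and 3244 without CD103+ replicate 2. The count for stromal macrophages and CD11b+ cells was 2054 without CD11b+ replicate 1 and 2210 without CD11b+ replicate 2. The count for CD103+ and CD11b+ cells was 1542 without CD103+ replicate 1, 1464 without CD11b+ replicate 1, 1965 without CD103+ replicate 2 and 1423 without CD11b+ replicate 2. The count for CD103- and CD11b+ cells was 1590 without CD103- replicate 1, 1315 without CD11b+ replicate 1, 1817 without CD103- replicate 2 and 1222 without CD11b+ replicate 2.

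Markers of cells that the sort should have left out were summed in each library. Summed over 12 luminal epithelial markers, the libraries stood at 255 and 505 CPM in ductal macrophages, 1161 and 2942 CPM in stromal macrophages, 1943 and 1037 CPM in CD103+ cells, 1262 and 527 CPM in CD103- cells, and 784 and 1922 CPM in CD11b+ cells (replicates 1 and 2). Of these, the keratin gene Krt19 stood at 47.6 CPM in ductal replicate 1 and 396 CPM in stromal replicate 2. The fibroblast sum ranged from 299 CPM in CD11b+ replicate 1 to 1646 CPM in stromal replicate 2, led by the collagen gene Col3a1 at up to 643 CPM in ductal replicate 2. The basal epithelial sum ranged from 78.7 to 458 CPM, the endothelial sum from 33.5 to 423 CPM and the adipocyte sum from 5.01 to 457 CPM, the last highest in both stromal libraries. Mast cell markers summed to 164 and 58.2 CPM in the stromal libraries, led by Cma1 at 61.7 CPM in replicate 1, and to at most 10.6 CPM elsewhere.

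B cell markers stood apart in CD103- replicate 2, where Ms4a1 was at 90.8 and Cd79a at 62.6 CPM, against 7.53 and 10.7 CPM in CD103- replicate 1 and at most 3.52 CPM in the other libraries. Ighm, also on that list, ranged from 72.2 CPM (CD11b+ replicate 2) to 1028 CPM (stromal replicate 1). Sums of T cell markers (2.96 to 16.0 CPM), natural killer cell markers (2.27 to 15.2 CPM), neutrophil markers (0 to 30.3 CPM) and erythroid markers (2.98 to 60.5 CPM) were low, and the neutrophil sum came mostly from Retnlg. The monocyte sum was highest in CD11b+ cells, at 1452 and 1056 CPM, of which Ccr2 made up 1407 and 1014 CPM. The plasmacytoid dendritic cell sum ranged from 71.8 to 406 CPM, and Siglech, which is also on the microglia-type list, stood at 219 and 189.9 CPM in the ductal libraries.

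**Figure D4:**
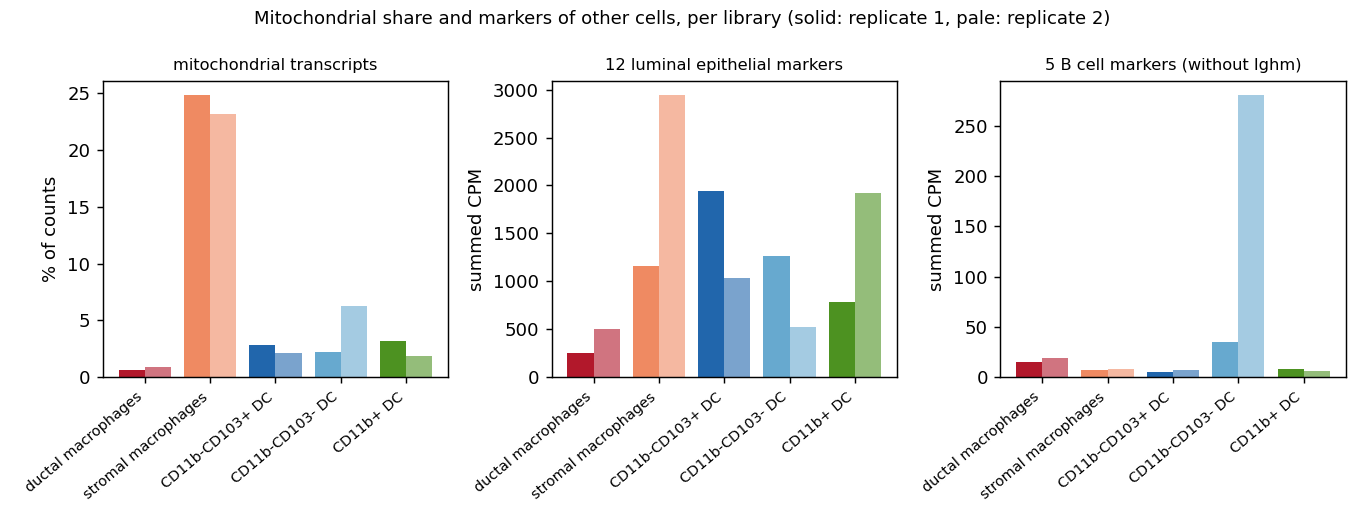
Mitochondrial transcripts as percent of counts, summed CPM of 12 luminal epithelial markers and summed CPM of 5 B cell markers (Ighm left out) for each library, with bars from 0, solid for replicate 1 and pale for replicate 2. Mitochondrial shares are highest in the stromal macrophages (24.8% and 23.1%), luminal markers differ between replicates of each population, and the B cell markers are highest in CD103- replicate 2.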

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

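The settings without mitochondrial genes, with thinned counts and with the epithelial level as a covariate were chosen after the data were seen, and the others before the data were examined. Of 220 results for named genes, 208 kept direction and call in every alternative, 0 turned direction and 12 lost the call in at least 1. Limma voom ended the calls of Apol7c (adjusted p = 0.0621), Igkc (0.165) and Tnfrsf4 (0.120) in ductal macrophages against dendritic cells, of Ighg2c (0.199) in CD11b+ cells, of Clec4n and Ms4a6d in CD103+ cells, and of ATP6 (0.119) in ductal macrophages against each. DESeq2 ended those of Adamdec1 (0.779) and B3galt5 (0.186) in ductal macrophages against each, and the test against a 1.5-fold change those of ATP6 (0.0660 by edgeR), Clec4n and Ms4a6d, the last 2 also in a fit of the compared populations only. DESeq2 size factors, the stricter filter, thinned counts and the fit without mitochondrial genes left all 20 counts of calls within 1.5 times. Mitochondrial gene removal left 1 named-gene value, that of ATP6, without a result. Of 100 list results, 68 were calls and all were lost with an estimated correlation, while 12 were lost and 7 gained with fry, 5 lost and 6 gained with the epithelial covariate, 6 lost and 2 gained with thinned counts, and 2 lost and 2 gained with the replicate block. Among list results with a library left out, 557 stayed, 26 lost and 16 gained a call, and 1 turned direction. That list, lipid handling in CD103+ against CD103- cells, had a camera adjusted p of 0.962 without CD103- replicate 2 (range 0.000234 to 0.962 over left-out libraries).

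Against a 1.5-fold change, fewer genes passed, as that test asks for more. The counts were 1460 lower in ductal than stromal macrophages, 1444 higher and 1095 lower in ductal macrophages than dendritic cells, 1982 higher and 1832 lower in stromal macrophages than dendritic cells, 3 higher in CD103+ cells, 1166 higher and 855 lower in CD11b+ cells, and 229 above and 108 below each population in ductal macrophages. Pairs gave 2374 (ductal and CD103+), 2313 (ductal and CD11b+), 2632 (stromal and CD11b+), 1755 (CD103+ and CD11b+) and 1505 (CD103- and CD11b+). For genes higher in CD103+ cells the count was 106 with no filter, 119 with DESeq2, 3 with voom, 3 with the compared populations only, 3 with the replicate block and 17 with the epithelial covariate, and for genes lower it was 44, 31, 1 and 1 in the first 4 of these. Below each population, ductal macrophages had 281 genes with no filter, 294 with DESeq2 and 90 with voom, and above each 614 with DESeq2. Voom called 1074 genes lower in ductal macrophages than dendritic cells, and stromal macrophages and CD103- cells differed at 3430 genes in a fit of those populations only. For these changes the cause was not tested, nor for those that follow.

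With 1 library left out, where the lone library was assumed to vary like the other groups, counts ranged from 1555 to 2425 (higher in ductal than stromal macrophages), 981 to 2002 (lower), 1230 to 2231 (higher in ductal macrophages than dendritic cells), 755 to 1685 (lower), 2 to 18 (higher in CD103+ cells), 0 to 11 (lower), 1141 to 2032 (higher in CD11b+ cells), 558 to 1541 (lower), 123 to 414 (ductal macrophages above each) and 58 to 197 (below each). Pairs ranged from 1714 to 2514 (ductal and CD103+), 1914 to 2708 (ductal and CD103-), 1740 to 2385 (ductal and CD11b+), 3244 to 5300 (stromal and CD103+), 2054 to 3645 (stromal and CD11b+), 1423 to 1965 (CD103+ and CD11b+) and 1222 to 1817 (CD103- and CD11b+). The replicate numbers did not pair the libraries across all populations. Correlations of replicate differences were 0.102 to 0.126 among ductal macrophages, stromal macrophages and CD11b+ cells, and 0.177 between CD103+ and CD103- cells. Every correlation between these sets was negative (-0.176 to -0.124). The luminal markers described below divided the populations in the same way, and a batch shared under unequal replicate numbers was not tested. The replicate block, which joins equal numbers, moved 1 of 20 counts by over 1.5 times. In CD103+ against CD103- cells it ended the calls of Itgae (adjusted p = 0.0578 by edgeR, log2 fold change 4.76) and Ms4a6d (0.124, 2.37), and in ductal macrophages against each population that of ATP6 (0.0816, -3.74). Distances from ductal macrophages rose to 2.25, 2.06, 2.08 and 2.01 at a prior count of 0.5 (stromal, CD103+, CD103- and CD11b+) and fell to 1.71, 1.57, 1.60 and 1.55 with thinned counts.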

Other observations

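Of the tests in this part, only that of nuclear respiratory chain genes was chosen before its result was seen. All 15 mitochondrial genes were higher in stromal macrophages than in dendritic cells and than in ductal macrophages by edgeR, with median log2 fold changes of 3.32 and 4.85. More mitochondria per cell were assumed, without a test, to raise the nuclear genes of the respiratory chain by about as much. Their median against dendritic cells was 0.19 (76 genes, quartiles -0.09 to 0.43, 9 higher and 2 lower). It lay between the bounds set beforehand for and against this cause, so the preset rule did not decide. These quartiles lay far below the mitochondrial median of 3.32, which, under that assumption, argued against a rise of similar size. That reading was not set beforehand. Carry-over of mitochondrial ribosomal RNA was argued against by the 13 protein-coding transcripts, whose median was 3.13. Loss of cytoplasmic RNA with nuclei kept was argued against by 5 nuclear-retained RNAs, with a median of -0.99 against dendritic cells and -0.25 against ductal macrophages, although Malat1 (0.96) and Neat1 (1.42) lay above the ductal level, and what raised the mitochondrial transcripts stays open.

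Luminal epithelial transcripts differed between replicates as a block. All 11 tested luminal markers were higher in replicate 2 of ductal macrophages and of CD11b+ cells, 10 were in stromal macrophages, and 0 in CD103+ and in CD103- cells. The library explained 81.2% of the variance of their replicate differences, against a median of 9.98% for 10000 random lists matched on expression, a percentile of 100, which restates the pattern and decides nothing about its source. The basal epithelial, endothelial and adipocyte sums moved between replicates in the same direction as the luminal sum in every population. The basal sum, for example, went from 97.9 to 190 CPM in ductal macrophages and from 458 to 186 CPM in CD103+ cells. The fibroblast sum did so in all but CD103+ cells. These joint movements go with carry-over, but they were read after the data were seen and do not test the source. Epithelial RNA or cells carried over in varying amounts were neither shown nor excluded and stay open. No biological explanation was tested.

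Macrophage genes were higher in CD11b+ than in CD11b- dendritic cells. If stromal macrophages had been mixed into the sort, 19 macrophage core genes, chosen among those called higher in CD11b+ cells, would imply a median share of 43.7%. Over 35 genes abundant in stromal macrophages the lower quartile was 0.546%, the median 10.3% and the upper quartile 48.6%, and 15 of them implied under 5%. Lyve1 stood at 570.4 CPM in stromal macrophages and 0.840 CPM in CD11b+ cells. For ductal macrophages, 20 core genes chosen in the same way implied 26.1%. Over 44 abundant genes the lower quartile was -0.182%, the median 3.47% and the upper quartile 19.4%, with 24 under 5%. Such uneven shares argued against either mixture, of cells like the sorted average, as the source of the whole difference. A minor share or a subset of those macrophages was not excluded. Monocytes in the sort may contribute and stay open, because monocyte transcripts such as Ly6c2 and Plac8 (median log2 fold change -2.69) were already present in the CD11b- cells, and expression by the CD11b+ cells themselves is a hypothesis that was not tested.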
